A study of Homo sapiens with 4 samples.

How the data were processed

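RNA-seq libraries of THP-1, an established human monocytic leukaemia cell line, were compared between cells that received a lentivirus with a scrambled short hairpin RNA (shRNA) and cells that received a lentivirus with an shRNA against PIWIL4. Each group held 2 libraries, numbered 1 and 2 in the sample titles, which also mark them exp. rep1 and exp. rep2 in both groups. Per the labels' protocols, the transduced cells were sorted 48 hours after transduction and libraries were made from total RNA with an Illumina TruSeq RNA kit. Groups were taken from the sample titles, because the treatment label of the shPIWIL4 libraries uses the word scrambled as well as PIWIL4. The labels name no date, batch or sequencing run, and do not say whether the replicates came from separate cultures. P-values therefore measure the spread between these samples, which may be technical.

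Per the submitters' processing notes, the tools were STAR, featureCounts and DESeq2 and the genome build was hg19. Their versions, the gene annotation and the strand setting are not given in the sources used here. The deposited table of each library holds a raw read count per gene, with FPKM and TPM values that the authors derived from it. All 4 tables list the same 25680 gene names in rows. The deposited table of the whole series holds a normalized signal, which was found to be the count divided by 1 size factor per library. Those factors matched the DESeq2 size factors computed here from the counts, 0.695 and 1.17 for Scrambled libraries 1 and 2 and 1.10 and 1.13 for shPIWIL4 libraries 1 and 2. The FPKM values were used only to recover gene lengths, all of which came out within 0.01 of a whole number. The TPM values and the normalized signal entered no test.

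Total counts were 31458079 and 51655687 for Scrambled libraries 1 and 2, and 50689304 and 53657246 for shPIWIL4 libraries 1 and 2. In the tables, 28 gene names had been turned into dates by spreadsheet software. These were tested but are not named. No mitochondrially encoded transcript was matched by name, and this class is not analysed here. No genome of the authors' build was used, so no coordinates are given. Without a stated strand setting, reads of overlapping antisense genes cannot be told apart, and histone, ribosomal protein, metallothionein and HSPA7 counts are uncertain because near-identical copies or pseudogenes can share reads.

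Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 16108 genes. Another 4634 genes with at least 1 count were left out by the filter, and 4938 genes were at 0 in all 4 libraries. TMM factors scaled the libraries, and the robust quasi-likelihood F test compared shPIWIL4 with Scrambled with group as the only term. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM values are scaled by TMM and given as mean and SD over 2 libraries. TMM assumes that most genes do not change between groups. Because 57.7% of tested genes were called here, directions are relative to the centre of all tested genes, and a change in total RNA per cell could not be seen.

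Gene lists were fixed before the data were examined, 29 in all with 1026 members, of which 1011 were matched by name and 23 of those through an older symbol. A list was tested where at least 5 members were tested, which held for 28 lists. The list test was limma 3.58.1's camera on voom values with a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera was repeated with the correlation estimated for each list, a test with 2 degrees of freedom here. Camera compares a list with all other genes tested. For each list, calls are given over all genes tested and adjusted over the list alone. The named genes were fixed by a rule. They are PIWIL4, the 12 largest positive and 12 largest negative log2 fold changes among called genes with a mean of at least 10 CPM in the higher group and groups that do not overlap, and up to 4 called members of each list with the smallest p. Names of unnamed loci were left out, among them clone-style names.

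Replicates were compared before they were averaged. Over 15764 and 15582 genes with a total of at least 20, the chi-square per gene was 7.91 between the Scrambled libraries and 28.0 between the shPIWIL4 libraries, so both pairs differed by more than sampling noise. The methods were tested on simulated counts drawn from the means and library sizes of this comparison, with 50 genes changed at each of 4 fold sizes among 15903 genes. The test recovered 12% of genes changed by 1.25-fold, 64% at 1.5-fold, 94% at 2-fold and 96% at 4-fold, and 15 of 148 calls were false. With no change simulated over 15920 genes, 1 gene and 0 lists were called. Genes were drawn independently of each other, so this could not show false list calls that arise from correlation between genes.

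Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, DESeq2 size factors, upper-quartile factors, no filter, a stricter filter of 5 CPM in 2 libraries, each library left out in turn, the replicate number as a block, a fold threshold of 2, a test against a 1.5-fold change, fry, and camera on members of 1 list only. Library totals in place of TMM, a loess offset for gene length and GC content, and a crossed pairing were added after seeing the data. GC values, from a transcript annotation of another build matched by gene name, were found for 92.9% of tested genes.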

Results

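Gene expression was measured by RNA-seq in THP-1 cells, a human monocytic leukaemia line, after transduction with a scrambled shRNA (n = 2 libraries) or an shRNA against PIWIL4 (n = 2 libraries). PIWIL4 is a member of the PIWI family of Argonaute proteins, which bind small RNAs in the germline. Total counts per library ranged from 31458079 to 53657246. The comparison asked how gene expression differs in AML cells when PIWIL4 is knocked down, in a study that deals with PIWIL4, R-loops and genome integrity.

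PIWIL4 was lower in both shPIWIL4 libraries. Its level was 38.5 and 37.2 CPM in Scrambled libraries 1 and 2, from 1223 and 1963 counts, and 17.8 and 17.4 CPM in shPIWIL4 libraries 1 and 2, from 902 and 904 counts. The means were 37.8 ± 0.93 CPM and 17.6 ± 0.29 CPM (SD, n = 2 each). PIWIL4 fell by 1.10 on the log2 scale (SE 0.09), which is 2.15-fold lower, with an adjusted p of 1.3e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

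**Figure D1:**
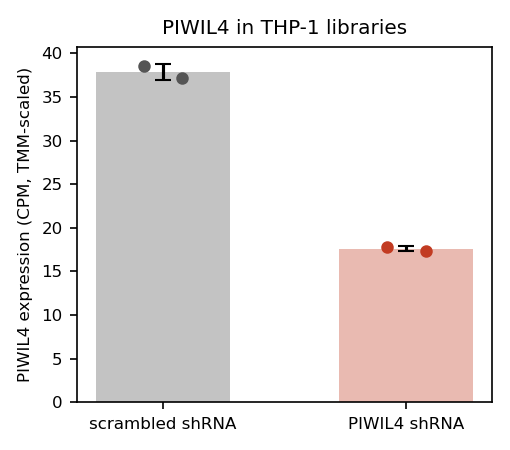
PIWIL4 expression in CPM in the Scrambled and shPIWIL4 libraries. Bars are group means, error bars are the SD over 2 libraries and points are single libraries, which sit at 38.5 and 37.2 CPM in Scrambled and at 17.8 and 17.4 CPM in shPIWIL4.

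In the shPIWIL4 libraries, transcripts for oxidative phosphorylation, interferon-stimulated genes, histones and cell cycle genes were higher, together with the macrophage genes LYZ, CD36 and TREM2. Monocyte and macrophage genes moved both ways, with 21 of 41 list members higher and 8, among them ITGAX, lower. Transcripts for cytosolic ribosomal proteins, glycolysis, cholesterol synthesis, immediate early genes and inflammatory genes were lower. These list calls came from camera with a preset correlation of 0.01 between genes. With an estimated correlation, a test with 2 degrees of freedom, 0 lists were called, and the smallest camera adjusted p was 0.28. For some called lists, such as histones (-0.033) and cholesterol synthesis (-0.029), the estimate lay below the preset value. For others, such as G2/M genes (0.34), it lay above. A larger correlation alone therefore does not account for all the lost calls. Among single genes, LYZ, which encodes lysozyme, rose from 147 ± 5.6 to 1810.2 ± 10 CPM, and SLC2A3, a glucose transporter gene, fell from 76.0 ± 0.25 to 3.57 ± 0.42 CPM (SD, n = 2 each). Of 16108 genes tested, 4618 were higher and 4683 were lower in shPIWIL4, which is 57.7% of the genes tested. At least a 2-fold change was found for 771 of the higher and 1824 of the lower genes, and at least a 4-fold change for 107 and 502. The groups did not overlap for 78.6% of tested genes, where chance gives 33.3% for 2 libraries against 2. With upper-quartile factors 3446 genes were higher and 5717 lower, so that 37.6% of calls were higher against 49.7% with TMM, as this scaling moved the median log2 fold change of all genes to -0.12. The labels give no batch, so a batch that followed the groups cannot be told apart from the shRNA. No group with another shRNA against PIWIL4 or with PIWIL4 restored was included. Effects of lower PIWIL4 therefore cannot be told apart from other effects of the shRNA.

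**Figure D2:**
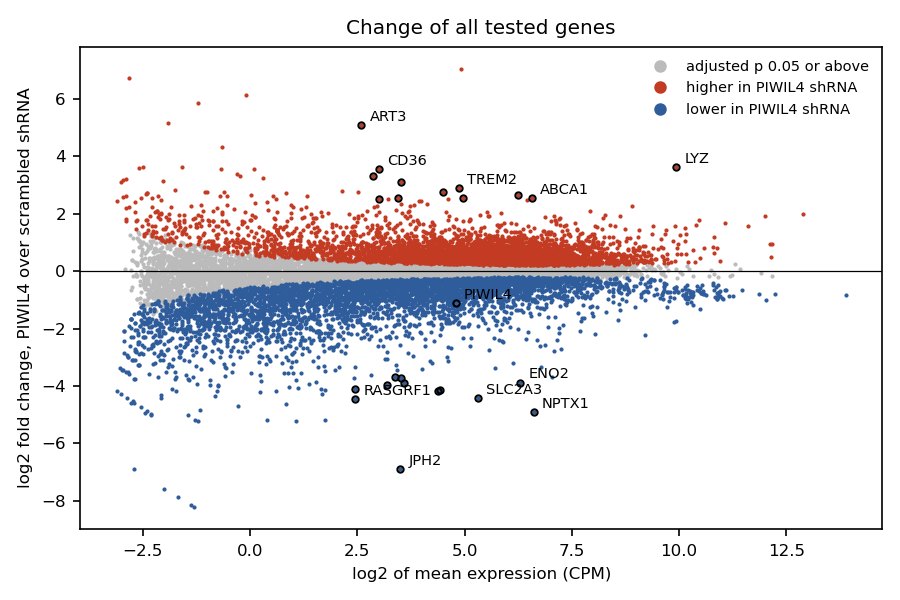
Log2 fold change of PIWIL4 shRNA over scrambled shRNA against the log2 of the mean CPM, for 16108 genes. Red points are the 4618 higher and blue points the 4683 lower genes at an adjusted p under 0.05, grey points are the other genes, and circles mark PIWIL4 and the 24 genes with the largest changes under the naming rule.

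The largest rise under the naming rule was in ART3, which went from 0.306 ± 0.21 to 11.7 ± 0.92 CPM, a log2 fold change of 5.10 (SE 0.25). LYZ rose by 3.62 (SE 0.10) and the scavenger receptor gene CD36 by 3.57 (SE 0.17). TREM2, a lipid-sensing receptor of macrophages, rose from 6.91 ± 0.29 to 51.6 ± 0.88 CPM. SIGLEC1, a sialic acid receptor of macrophages, rose from 5.79 ± 0.57 to 39.5 ± 3.3 CPM, and ABCA1, a cholesterol efflux transporter, from 27.7 ± 0.091 to 162 ± 6.2 CPM. PDGFD, FRMD3, TCHH, IQGAP2, MT1F and SCG3 completed the 12 rises, with log2 fold changes of 3.30, 3.09, 2.65, 2.55, 2.54 and 2.53. MT1F is a metallothionein whose copies resemble each other, so its value is uncertain. The clone-named locus FLJ36000, which the naming rule left out and which was chosen after its values were seen, rose by 7.05, from 0.435 ± 0.081 to 59.6 ± 2.7 CPM. For these genes the adjusted p of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was at most 9.4e-07, the value of SCG3.

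The largest fall was in JPH2, a junctophilin gene, from 22.3 ± 2.1 to 0.185 ± 0.066 CPM, a log2 fold change of -6.89 (SE 0.21). NPTX1, a neuronal pentraxin gene, fell from 189 ± 8.8 to 6.29 ± 0.18 CPM (-4.91, SE 0.10). RASGRF1, a Ras exchange factor gene, fell by 4.45 (SE 0.17), SLC2A3 by 4.41 (SE 0.11) and NFATC4, a transcription factor gene, by 4.18 (SE 0.12). The arginase gene ARG1 fell from 40.6 ± 1.4 to 2.31 ± 0.19 CPM, the osteopontin gene SPP1 from 22.4 ± 0.21 to 1.5 ± 0.33 CPM, and the enolase gene ENO2 from 146 ± 4.6 to 9.89 ± 0.73 CPM. HSPA7, PPL, SLC44A2 and VAT1L had log2 fold changes of -4.12, -3.96, -3.71 and -3.69. HSPA7 is nearly identical to HSPA6, and its value is uncertain. The largest adjusted p among these 12 genes was 3.5e-07, that of HSPA7, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

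**Figure D3:**
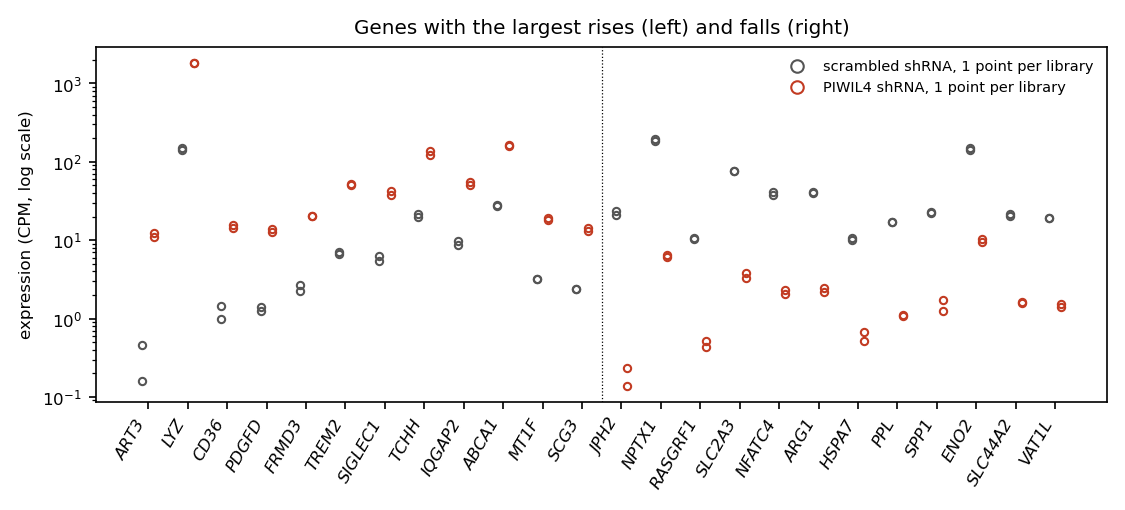
CPM on a log axis of the 12 genes with the largest rises (left) and the 12 with the largest falls (right), with 1 point per library. For every gene shown both shPIWIL4 libraries lie on the same side of both Scrambled libraries, as the naming rule requires.

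Genes for R-loop resolution were higher in shPIWIL4 by a small amount. Of 38 members, 18 rose and 0 fell, and the counts adjusted over the list alone were also 18 and 0. The median log2 fold change was 0.25. The mRNA export genes DDX39A and ALYREF rose by 0.82 (SE 0.10) and 0.80 (SE 0.10), the ribonuclease H2 subunit gene RNASEH2B by 0.76 and the helicase gene AQR by 0.78. With upper-quartile factors the median was 0.12, with 14 higher and 2 lower. The list had an adjusted p of 1.1e-03 in camera and an adjusted p = 0.32 with an estimated correlation. In the ATR and replication stress list, 17 of 25 members rose and 2 fell, with 17 and 2 adjusted over the list alone. CDC25A, a cell cycle phosphatase gene, rose from 50.1 ± 1.6 to 113 ± 8.8 CPM, and ATRIP, RPA3 and WDHD1 rose by 0.82, 0.65 and 0.57. In camera the list had an adjusted p of 1.9e-03, and the adjusted p = 0.39 with an estimated correlation.

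Homologous recombination and Fanconi anaemia genes moved both ways. Of 31 members, 13 rose and 5 fell, with 13 and 6 adjusted over the list alone, and the list was not called (camera adjusted p = 0.17). With upper-quartile factors 9 were higher and 8 lower, with a median log2 fold change of 0.07 against 0.19. Lower members numbered 8 with library totals or the stricter filter and 3 without Scrambled library 1 or without Scrambled library 2. The nuclease gene EXO1 rose by 0.96, RBBP8 by 0.65 and PALB2 by 0.64, and the DNA damage kinase gene ATM fell from 175 ± 8.1 to 102 ± 10 CPM. Among 29 tested p53 target genes, 9 rose and 8 fell, with 11 and 8 adjusted over the list alone (camera adjusted p = 0.41). The death receptor genes FAS and TNFRSF10B had log2 fold changes of 1.46 and -1.17, CCNG1 fell by 0.96 and AEN rose by 0.87. Among 35 apoptosis regulators, 10 rose and 14 fell, with 11 and 14 adjusted over the list alone (camera adjusted p = 0.48). Without Scrambled library 2, 8 were higher and 9 lower, and with upper-quartile factors 9 and 17. BCL2, an inhibitor of apoptosis, fell from 144 ± 2.7 to 61.4 ± 1.5 CPM, CFLAR fell by 0.85, and BCL2L11, which promotes apoptosis, rose by 0.82.

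The PIWI and piRNA pathway list was not called (camera adjusted p = 0.48). Of 14 tested members, 4 rose and 5 fell, with a median of -0.27 that was 0.24 over the 9 members left by the stricter filter, and the counts adjusted over the list alone were the same. The counts were 5 higher and 3 lower without Scrambled library 1, 1 and 5 without Scrambled library 2, and 2 and 6 with upper-quartile factors. Besides PIWIL4, TDRD5 fell from 1.35 ± 0.091 to 0.252 ± 0.13 CPM and PIWIL2 from 0.807 ± 0.016 to 0.175 ± 0.0031 CPM, both at low levels, and the arginine methyltransferase gene PRMT5 rose by 0.42. Of 34 genes for H3K9 methylation and transposon silencing, 7 rose and 13 fell, with 7 and 13 adjusted over the list alone (camera adjusted p = 0.59). Their median log2 fold change was 0.013, their mean was -0.098 and camera's direction was down. The median was also negative with library totals (-0.033), upper-quartile factors (-0.11), a stricter filter (-0.047), the length and GC offset (-0.0064), without Scrambled library 2 (-0.0067) and without shPIWIL4 library 2 (-0.036), so its sign is not settled. FAM208A, KDM4C and the DNA methyltransferase gene DNMT3A fell by 0.94, 0.81 and 0.77, and the histone methyltransferase gene SUV39H1 rose by 0.74.

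Cell cycle genes were higher. In the G1/S list 29 of 46 members rose and 1 fell, and in the G2/M list 32 of 49 rose and 1 fell, with the same counts adjusted over the list alone. Without Scrambled library 2, 20 of the G2/M genes were higher and 0 lower. The median log2 fold changes were 0.33 and 0.32. POLA2, ORC6, E2F1 and FEN1, genes of DNA replication and its control, rose by 0.82, 0.79, 0.82 and 0.63. The cytokinesis gene ANLN rose from 144 ± 6.6 to 338 ± 33 CPM, and FOXM1, ECT2 and CCNA2 rose by 0.81, 0.86 and 0.70. The camera adjusted p was 1.8e-05 for G1/S and 2.4e-06 for G2/M, and the lists had an adjusted p = 0.32 and an adjusted p = 0.39 with an estimated correlation. Of 29 tested replication-dependent histone genes, 23 rose and 1 fell, with 23 and 1 adjusted over the list alone, and the median was 1.80. DESeq2 called 10 higher and 0 lower, and the stricter filter left 4 members, of which 3 were higher. HIST1H2BK rose from 4.85 ± 0.32 to 26.6 ± 1.5 CPM, HIST1H1C from 2.83 ± 0.58 to 15.8 ± 0.26 CPM, and HIST2H2BE by 1.27. HIST1H2BJ rose by 4.32 at low levels, from 0.0536 ± 0.031 to 1.23 ± 0.033 CPM, so the size of its change is uncertain. The histone list had a camera adjusted p of 5.2e-06 and an adjusted p = 0.28 with an estimated correlation, and counts of single histone genes are uncertain. Whether the rise of histone transcripts is tied to the cell cycle was not tested.

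Cytosolic ribosomal protein transcripts were lower as a group. Of 77 tested members, 75 fell and 1 rose, with the same counts adjusted over the list alone, and the median log2 fold change was -0.73. RPL15 fell from 1583 ± 9.1 to 735 ± 0.31 CPM and RPL3 from 2762 ± 24 to 1414 ± 24 CPM, and RPL37 and RPL29 fell by 1.34 and 0.99. These transcripts held 12.5% and 11.8% of all counts in Scrambled libraries 1 and 2, and 6.81% and 7.17% in shPIWIL4 libraries 1 and 2. Camera gave an adjusted p of 2.4e-16, and the adjusted p = 0.31 with an estimated correlation. Genes for ribosome biogenesis went the other way, with 24 of 46 higher and 1 lower, the same counts adjusted over the list alone, and a median of 0.29. NOP14, NIP7, GRWD1 and NOP2 rose by 0.79, 0.74, 0.68 and 0.61. By camera, the adjusted p was 1.3e-04 and the adjusted p = 0.31 with an estimated correlation.

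Nuclear-encoded oxidative phosphorylation transcripts rose in 70 of 76 members and fell in 0, with 70 and 1 adjusted over the list alone, and the median was 0.67. The cytochrome oxidase gene COX7C rose from 80.6 ± 6.5 to 239 ± 31 CPM, and the complex I genes NDUFB9, NDUFB10 and NDUFA6 rose by 1.28, 1.17 and 1.12. By camera, the adjusted p was 1.1e-15, and the adjusted p = 0.31 with an estimated correlation. Hypoxia and glycolysis genes fell in 25 of 32 members and rose in 1, with 26 and 1 adjusted over the list alone, and the median was -1.02. Besides SLC2A3 and ENO2, PFKFB4, a regulator of glycolysis, fell from 200 ± 2.5 to 19.7 ± 1.2 CPM, and the aldolase gene ALDOC from 238 ± 7.5 to 34.9 ± 0.13 CPM. The list test (camera) had an adjusted p of 1.3e-10, and the adjusted p = 0.28 with an estimated correlation.

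Cholesterol biosynthesis genes fell in 22 of 25 members and rose in 1, with the same counts adjusted over the list alone, and the median was -0.88. HMGCS1, an early enzyme of the pathway, fell from 977 ± 5.4 to 211 ± 9.6 CPM, LSS from 323 ± 16 to 104 ± 12 CPM, and DHCR7 and INSIG1 by 1.49 and 1.45. An adjusted p of 4.4e-09 was found with camera, and the adjusted p = 0.28 with an estimated correlation.

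Interferon-stimulated genes rose in 32 of 49 members and fell in 3, with 33 and 3 adjusted over the list alone, and the median was 0.67. MX1 rose from 4.55 ± 0.023 to 22.1 ± 0.29 CPM, IFI6 from 10.3 ± 0.69 to 39.3 ± 0.33 CPM, and OAS3 by 2.01, all antiviral or interferon-induced genes. UBE2L6, which encodes an enzyme that attaches ISG15, fell from 17.7 ± 0.86 to 3.55 ± 0.47 CPM. The list had a camera adjusted p of 4.8e-07 and an adjusted p = 0.31 with an estimated correlation. Inflammatory and NF-kB target genes fell in 20 of 30 members and rose in 3, with the same counts adjusted over the list alone, and the median was -0.999. The chemokine genes CCL20 and CXCL8 fell by 3.72 and 3.06, the latter from 15.9 ± 0.80 to 1.90 ± 0.26 CPM, and IL23A and ICAM1 fell by 1.91 and 2.19. In camera the list had an adjusted p of 5.2e-05, and the adjusted p = 0.28 with an estimated correlation. Immediate early genes fell in 24 of 29 members and rose in 0, with the same counts adjusted over the list alone, and the median was -1.03. EGR1 fell from 83.0 ± 3.9 to 12.4 ± 1.4 CPM, and JUN, JUND and IER2 by 1.92, 1.59 and 1.46. Camera gave an adjusted p of 2.0e-08, and the adjusted p = 0.31 with an estimated correlation.

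Monocyte and macrophage genes moved both ways with more rises, 21 of 41 against 8 falls, with 21 and 9 adjusted over the list alone and a median of 0.27. Besides LYZ and TREM2, the lysosomal protease gene CTSB rose from 64.8 ± 1.8 to 215 ± 3.4 CPM, and the integrin gene ITGAX fell from 247 ± 0.95 to 67.3 ± 2.3 CPM. By camera, the adjusted p was 0.031, the adjusted p was 0.15 under a stricter filter, and the adjusted p = 0.31 with an estimated correlation. Granulocyte and granule genes rose in 9 of 16 members and fell in 2, with the same counts adjusted over the list alone and a median of 0.56. The granule protease gene CTSG rose from 3037 ± 14 to 12081 ± 436 CPM, SRGN from 3131 ± 42 to 6041 ± 314 CPM and DEFA4 by 0.91, and the myeloperoxidase gene MPO fell by 0.89. The list test (camera) had an adjusted p of 0.042, the adjusted p was 0.15 under a stricter filter, and the adjusted p = 0.31 with an estimated correlation. In the MLL-fusion and leukaemia stem cell list 17 of 31 members fell and 3 rose, with the same counts adjusted over the list alone and a median of -0.49, which was -0.23 over the 19 members left by the stricter filter. NYNRIN fell from 13.8 ± 0.52 to 2.59 ± 0.12 CPM, and NGFRAP1, SMIM24 and BCL2 by 2.31, 3.12 and 1.23. An adjusted p of 2.1e-03 was found with camera, and the adjusted p = 0.31 with an estimated correlation.

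The list of amino acid response and unfolded protein response genes was split, with 22 of 38 members higher and 12 lower, the same counts adjusted over the list alone, and a median of 0.31. The endoplasmic reticulum genes CRELD2 and PDIA4 rose from 26.9 ± 1.8 to 150 ± 19 CPM and from 167 ± 0.50 to 507 ± 3.9 CPM. The stress genes STC2 and DDIT4 fell from 19.2 ± 0.55 to 1.99 ± 0.063 CPM and from 63.2 ± 1.4 to 16.8 ± 0.40 CPM. In camera the list had an adjusted p of 0.027, and the adjusted p = 0.31 with an estimated correlation. Heat shock genes rose in 12 of 19 members and fell in 0, with the same counts adjusted over the list alone and a median of 0.28. HSPH1, HSPA8, STIP1 and HSPA4, which encode chaperones or a co-chaperone, rose by 0.77, 0.79, 0.51 and 0.64. Camera gave an adjusted p of 6.1e-03, and the adjusted p = 0.39 with an estimated correlation.

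Markers of other cell types were mostly at low levels and mostly lower in shPIWIL4. Epithelial and embryonic kidney line markers fell in 6 of 7 tested members, with 6 adjusted over the list alone and a median of -1.05, and LIN28B fell from 23.8 ± 0.11 to 11.5 ± 0.84 CPM and PAX8 from 6.47 ± 0.38 to 3.11 ± 0.21 CPM. That list had a camera adjusted p of 7.4e-03, an adjusted p of 0.064 with DESeq2 and 0.061 without shPIWIL4 library 2, and an adjusted p = 0.31 with an estimated correlation. The lists of B lymphoid, erythroid and megakaryocyte, T and NK lymphoid, and fibroblast and stromal markers were not called, with camera adjusted p of 0.051, 0.11, 0.17 and 0.22. Their calls were 1 higher and 5 lower of 6, 0 and 3 of 6, 1 and 4 of 9, and 2 and 6 of 10. The T and NK lymphoid calls became 0 and 1 with DESeq2 and 2 and 1 without Scrambled library 2, and the fibroblast median of -0.72 became 0.015 over 12 members with no filter. Adjusted over the list alone, the T and NK lymphoid list had 1 and 5, and the other 3 lists had the same counts. The B lymphoid genes CD79A and CD79B fell by 2.96 and 0.97 and PAX5 rose from 41.7 ± 1.6 to 62.8 ± 1.9 CPM. ITGA2B fell from 8.15 ± 1.2 to 1.12 ± 0.31 CPM, CD7 from 0.451 ± 0.19 to 0.0681 ± 0.013 CPM, and the collagen gene COL6A2 from 28.8 ± 4.2 to 8.46 ± 2.3 CPM.

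**Figure D4:**
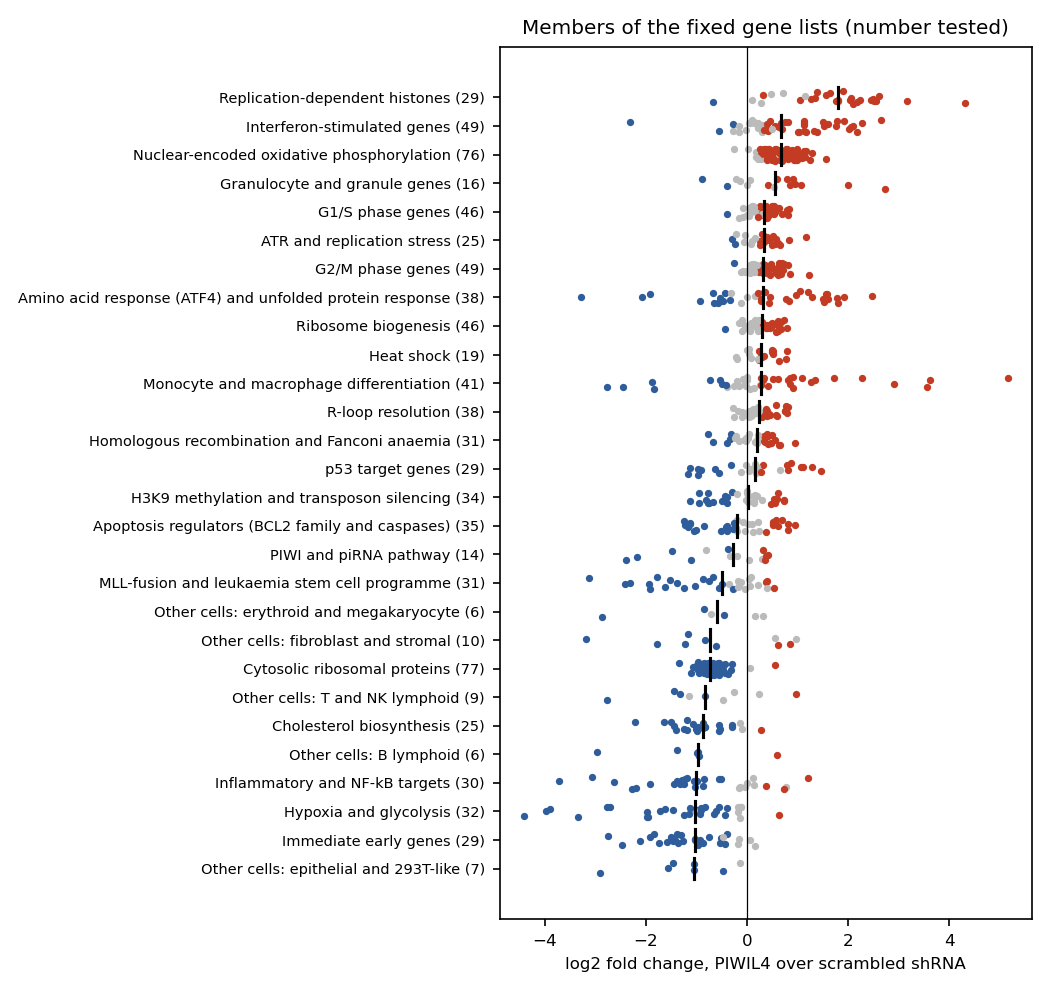
Log2 fold change of PIWIL4 shRNA over scrambled shRNA for each tested member of the 28 tested gene lists, with the number of members tested after each name. Red and blue points passed an adjusted p of 0.05, grey points did not, and black bars are list medians, which run from -1.05 for epithelial and embryonic kidney line markers to 1.80 for histones. The median of the H3K9 list, 0.013, turns negative with library totals, upper-quartile factors, a stricter filter, the length and GC offset, and without Scrambled library 2 or shPIWIL4 library 2.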

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

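Library totals, the offset for length and GC content and the crossed pairing were chosen after seeing the data. None of the 128 named genes, PIWIL4 not counted among them, and none of the 19 called lists changed direction under the alternatives run for them. The length and GC offset and the crossed pairing were not among these, and directions of the other called genes were not compared. For PIWIL4 the length and GC offset was compared and the crossed pairing was not. Among lists not called, camera's direction for the PIWI list turned from down to up with the stricter filter (adjusted p 0.861, range over alternatives 0.22 to 0.94), which left 9 of its 14 members, and the signs of the PIWI, H3K9 and fibroblast medians changed as given beside those lists. PIWIL4 stayed lower throughout, with log2 fold changes from -1.23 with upper-quartile factors to -1.06 without Scrambled replicate 1. The counts of 4618 higher and 4683 lower genes became 1106 and 1964 when tested against a 1.5-fold change, and 771 and 1824 at a fold of at least 2, because both ask for a larger change. With 1 library left out, 3573 to 5097 genes were higher and 3585 to 5074 lower, where the lone library of a group was assumed to vary like the other group. DESeq2 gave 4078 and 3764, limma-voom 4567 and 4658, DESeq2 size factors 4631 and 4660, upper-quartile factors 3446 and 5717, library totals 4120 and 4973, no filter 4985 and 4438, the stricter filter 3505 and 3351, and the length and GC offset 4894 and 5169. With the replicate number as a block, 3921 genes were higher and 4197 lower. Libraries with the same number had deviations with a correlation of -0.31. Their titles share an exp. rep number, but the labels name no day or batch that they share. A crossed pairing gave 5728 and 5641. Camera with an estimated correlation called 0 of the 28 tested lists, with a smallest adjusted p of 0.28 on 2 degrees of freedom. Fry called 24 of the 28 lists, 5 of them outside the 19. It asks whether a list's genes move and not whether they move more than other genes. The other settings called 15 to 22 lists. The stricter filter left 6 lists with too few members to test and ended the calls of the granulocyte list (adjusted p 0.15, range over alternatives 6.2e-04 to 0.31) and the monocyte list (0.15, range 3.0e-04 to 0.31). The epithelial list was lost with DESeq2 (0.064) and without shPIWIL4 replicate 2 (0.061), in a range of 7.5e-03 to 0.31. Upper-quartile factors lowered the medians of called lists with small changes: ATR from 0.33 to 0.21, G1/S from 0.33 to 0.21, G2/M from 0.32 to 0.20, ribosome biogenesis from 0.29 to 0.17, heat shock from 0.28 to 0.16, monocyte from 0.27 to 0.15 and the amino acid and unfolded protein response from 0.31 to 0.19. The B lymphoid list was also called with the replicate block (0.044), with no filter (0.046) and by fry (9.4e-03). Fry also called the apoptosis (adjusted p 0.011), fibroblast (0.020), T and NK lymphoid (0.039) and erythroid (0.04999) lists. Without Scrambled replicate 2 the B lymphoid, erythroid and fibroblast lists were called (0.039, 0.0497 and 0.043), in ranges of 9.4e-03 to 0.31, 0.0497 to 0.48 and 0.020 to 0.42. Without Scrambled replicate 2, higher and lower members went from 17 and 2 to 12 and 0 in the ATR list and from 3 and 17 to 1 and 15 in the MLL list. Without shPIWIL4 replicate 1 the ribosome biogenesis list went from 24 and 1 to 33 and 3. The cause of these list changes was not tested. Limma-voom gives no separate list result, because camera already uses voom values. Of 128 named genes, 22 lost their call in the test against a 1.5-fold change and 4 under another alternative. In counts simulated at these library sizes 64% of genes changed by 1.5-fold and 94% changed by 2-fold were found. Far fewer genes were changed in that simulation than were called in the data, so these rates need not hold for the data. Neither depth nor the number of replicates was varied there, so which of them limits small changes was not tested.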

Other observations

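The gene lists in this part, apart from the ribosomal protein list and the hypoxia and glycolysis list of the report, and all their tests here were chosen after the results for single genes had been seen. Of 36 endoplasmic reticulum chaperone, isomerase and translocation genes, 32 rose and 2 fell, with a median log2 fold change of 0.87; 13 of them are also in a list fixed earlier. HSP90B1, a chaperone gene, rose from 1698 ± 107 to 6429.9 ± 869.5 CPM, CALR from 1567 ± 29 to 4686 ± 342 CPM and DNAJB11 from 91.1 ± 1.4 to 393 ± 35 CPM (SD, n = 2 each). Of 43 tested lysosome and V-ATPase genes, 37 rose and 1 fell, with a median of 0.89. The cathepsin gene CTSD rose from 163 ± 14 to 793 ± 180 CPM and the membrane protein gene LAMP1 from 166 ± 6.5 to 623 ± 35 CPM. Camera gave an adjusted p of 5.1e-13 and 2.1e-14 for these lists, and both had an adjusted p = 0.27 with an estimated correlation.

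Proteasome subunit genes rose in 29 of 34 members and fell in 0 (median 0.58), and mitochondrial ribosomal protein genes rose in 45 of 76 and fell in 1 (median 0.35). All 5 tested metallothionein genes rose (median 2.34), among them MT1E from 5.71 ± 0.069 to 28.9 ± 4.0 CPM, with uncertain counts because the copies are alike. All 8 tested MHC class II presentation genes fell (median -0.85), CD74 from 253 ± 4.4 to 161 ± 4.5 CPM and its regulator CIITA from 10.4 ± 0.11 to 5.93 ± 0.19 CPM. The camera adjusted p was 4.4e-08, 1.2e-07, 2.6e-04 and 2.6e-04 in that order, and with an estimated correlation the adjusted p was 0.36 for the first 3 lists and 0.27 for MHC class II. MHC class I presentation genes (2 higher and 2 lower of 12), liver X receptor targets (5 and 3 of 11) and amino acid response genes (9 and 10 of 25) were not called, with camera adjusted p of 0.80, 0.56 and 0.56. The 25 amino acid response genes had a median log2 fold change of -0.042, and 22 of them are also in a list fixed earlier. Cytosolic aminoacyl-tRNA synthetase genes rose in 10 of 19 and fell in 3, with a camera adjusted p of 0.029 and an adjusted p = 0.63 with an estimated correlation.

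Of the tests that follow, those of culture conditions and of zinc finger genes against other genes of the same windows were written only after the values they measure had been seen. The fall of cytosolic ribosomal protein transcripts was not removed by an offset for gene length and GC content, with which the median was -0.86 and 75 of 77 were still lower. It was not shared by abundant transcripts in general, since 385 genes outside the list, 5 nearest in expression to each member, had a median of 0.18 at a median of 480 CPM, and 77 genes matched 1 to each member had 0.17 at 1116 CPM, against 1159 CPM for the ribosomal proteins. Transcripts outside the ribosomal proteins that carry a terminal oligopyrimidine tract, a motif that couples translation and stability to growth signals, fell in 19 of 28 members and rose in 3 (PABPC1, COX4I1 and EIF3K, named after their values were seen) with a median of -0.46 (camera adjusted p = 2.6e-04, adjusted p = 0.52 with an estimated correlation), which is consistent with a coordinated fall of this class as a hypothesis. EEF1A1 and TPT1, also of this class, were left out of the 28 because their values had been seen. Reads shared with pseudogenes were not tested.

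The fall of hypoxia and glycolysis genes extended to 36 further targets of hypoxia-inducible factors, of which 29 fell and 2 rose, with a median of -1.02 (camera adjusted p = 3.1e-10, adjusted p = 0.27 with an estimated correlation); 3 of them, among them DDIT4, are also in a fixed list. Lower activity of these factors in the shPIWIL4 cells may therefore be a candidate explanation. Targets already seen among the largest falls had been left out of the 36. The mean log2 CPM of the fixed list was 1.33 higher in Scrambled, against a largest difference of 0.060 within a group. A difference in oxygen or cell density between the cultures cannot be told apart from the shRNA, because the labels describe no culture variable that varies within a group.

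Copy number differences between the cell stocks were weighed for the breadth of the change: of 144 windows of 100 neighbouring genes, 1.39% (2 windows) lay 0.4 or more from the median of all genes, against 0 in shuffled orders, which argues against large gains or losses as the source of most calls. Smaller shifts stay open, since window medians had an SD of 0.135 against 0.072 in shuffled orders, neighbouring genes had a correlation of 0.19 against at most 0.027 (permutation p = 0.001, the smallest that 1000 shuffles can give), and the 5 lowest windows, at -0.65, -0.52, -0.396, -0.29 and -0.27, all lay on chromosome 19, 4 of them side by side. All 11 windows of that chromosome lay below the median of all genes. Zinc finger genes with ZNF names fell there in 171 of 233 and rose in 1, against 82 lower and 42 higher of 240 on other chromosomes, but other genes of the 2 lowest windows also fell more often than they rose (58 lower and 24 higher of 130, median -0.33), as did other genes of chromosome 19 outside them (310 and 179 of 820, median -0.14). An offset for length and GC content left the median of all ZNF genes at -0.41, which argues against that trend as the whole cause, while a lower copy number on chromosome 19 cannot be told apart from regulation of these genes: ZNF genes on other chromosomes had a median of -0.11, between the bounds set for that test, and the difference of -0.56 between ZNF genes and other genes of the 2 lowest windows decides nothing, because windows and genes were picked for low values and ZNF genes lie in clusters that a loss within a window might cover.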
